A study of Sus scrofa with 4 samples.

How the data were processed

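The labels describe 4 single-cell RNA libraries of pig aortic valve interstitial cells made on the 10x Chromium system, 1 each for control, NO donor, NO withdrawal and S-nitrosoglutathione. The submitters' processing notes name Cell Ranger, Seurat 3.0, DESeq2 and the pig build Sscrofa11.1, without the role of each. The values used came from the authors' deposited table of a DESeq2 comparison of the NO donor with the control, with 14804 gene rows. Per the file headers, the table holds 3 columns of normalized counts for each of the 2 libraries. The withdrawal and S-nitrosoglutathione libraries had no column in it and were not analysed here.

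The normalized count columns and the mean over them hold a signal that the authors scaled by a size factor per column, per the file headers and the values. In each of the 6 columns 100% of values were whole multiples of 1 step within 0.01, so the whole counts were recovered. The step gave size factors of 1.23, 1.23 and 1.22 for the NO donor columns and 0.743, 0.823 and 0.926 for the control columns. The deposited mean equalled the mean of the 6 columns. The log2 fold change and its standard error on the log2 scale are the authors' estimates of NO donor over control, per the file headers. The Wald score in the authors' table is the fold change over that error. The p-value and adjusted p-value in the authors' deposited table come from DESeq2, per the file headers, over the 6 columns. How cells were filtered, how doublets were treated, how the 3 columns were made and which gene annotation was counted were not given in the sources used here. Whether the columns are parts of the cells, separate captures or separate cultures therefore stayed open, and they were treated as parts of the 1 library that the labels give each group.

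For each gene the 3 recovered counts of a library were summed and divided by the sum of the 3 size factors, which gives the normalized counts reported. The log2 ratio is the NO donor value over the control value, with no pseudocount. A library with 0 counts was set to a floor of 3 counts, and the ratio then is a bound at that floor. The 95% intervals are exact Poisson intervals for a level and exact binomial (Clopper-Pearson) intervals for a ratio, conditional on the summed count, and both cover counting error only. The totals of 21289316 and 21807024 counts per library make these intervals narrow for abundant genes; variation between cultures is not in them and was not measured. Spread between columns was measured as the chi-square of the 3 counts around their expected shares over its degrees of freedom.

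Genes were taken as measured where the authors' deposited table gives an adjusted p-value, which 13943 rows have and 861 lack; the lowest mean among them was 1.42. A gene of a list was called higher or lower at an absolute log2 ratio of 0.5 or more, a rule of size. The 34 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 highest and the 10 lowest log2 ratios among genes with a symbol, an adjusted p below 0.05 in the authors' deposited table and a mean at or above the median of measured genes, 91.7. USP9X, NOTCH1 and the measured NOTCH targets were added, with up to 4 members of each list with the largest absolute log2 ratio at or above that mean, 132 genes in all; the text gives a part of them, and 1 result is not reported here. For each list with at least 5 measured genes, the median log2 ratio was placed among 10000 random lists of the same size drawn within 20 bins of mean expression. Lists of cardiomyocyte markers, with 4 measured genes and a median of 0.08, and of epithelial markers, with 1 and a value of 1.39, got no percentile. The permutation p of each list that had been planned is not printed, since genes are not replicates. Because the table held 1 library per group, no gene test of the treatment was made, and counts past the authors' adjusted p-value are given only as a property of their table.

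Symbols were matched exactly to the RefSeq annotation of Sscrofa11.1, the build the submitters' processing notes name, and 14775 rows matched. Coordinates are 1-based gene spans of that annotation, exons and introns together. Of the rows, 19 carried names that a spreadsheet had turned into dates, 10 carried a suffix for a repeated name and 2262 were uncharacterised loci; none of these was named. Ribosomal protein genes and metallothioneins have near-identical copies, and reads shared among copies make their single values uncertain. MMP3 and CXCL8 are given under the names in the table.

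The alternatives were other thresholds on the authors' adjusted p-value, a minimum fold change, other filters on the mean, the mean in place of the median of a list, unmatched and more finely matched random lists, the Wald score, and lists without their most extreme member. Scaling by edgeR's TMM and by total counts, the authors' fold change in place of the ratio of sums, size counts with no minimum mean, and edgeR's quasi-likelihood test on the recovered counts were added after seeing the data. The list step was tested on simulated data of 13943 genes: 6.5% of unshifted lists fell outside the central 95%, and 99.5% and 100% did at shifts of 1 and 2 log2 units. The ratios were shuffled over genes and the lists drawn at random. These list rates therefore do not cover real lists, whose genes can vary together. The count test, also tested on simulated data of 13943 genes, recovered 100% of genes set to 2-fold, with 5.21% of calls false. Those data were Poisson counts in independent columns. The real columns spread more widely, so these rates cannot be carried over to calls on the real counts. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.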

Results

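The series examined primary interstitial cells of the pig aortic valve (Sus scrofa), the fibroblast-like cells that maintain the valve matrix and that are studied as a source of calcifying cells. The series title ties nitric oxide (NO) to valve calcification through S-nitrosylation of USP9X, a deubiquitinase, and NOTCH signalling. The labels give 4 droplet single-cell libraries, 1 per group, each aimed at about 2000 cells after 5 days of culture. The groups were an untreated control, the NO donor detaNONOate at 150 µM for 5 days, the same donor for 3 days followed by 2 days without it, and the S-nitrosylation donor S-nitrosoglutathione at 200 µM for 5 days. Only the NO donor and control libraries were compared; the withdrawal and S-nitrosoglutathione libraries were not analysed here.

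The values were counts per gene, with no cell by cell values, given as 3 columns for each library. The columns held 7064703, 7151367 and 7073246 counts for the NO donor, 21289316 in all, and 6486628, 7252735 and 8067661 for the control, 21807024 in all. How the 3 columns of a library were made was not given in the sources used here. They were taken as parts of 1 library, so each group had 1 library, the differences had no replicate check, and no test of the treatment was made. Ratios carry exact 95% intervals that cover counting error only. The spread of the columns was 1.37 times that of Poisson counting in the NO donor library and 1.35 times in the control over genes with at least 5 expected counts per column. It was wider for some groups of genes, for which the median of each gene's own spread was taken. In the control this median was 9.82 over the contractile list, 5.68 over the G2/M cell cycle list and 3.75 over the ribosomal protein list. Such a median is not on the same scale as a value pooled over genes. Over genes with a mean of at least 1000 counts per column the pooled spread was 3.30 times that of Poisson counting in the NO donor library and 3.50 times in the control. All 8 counts of MYH11 in the NO donor library lay in 1 column. The counting intervals of such genes, abundant ones included, are therefore too narrow.

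The comparison of the NO donor with the control asked which genes differed in valve interstitial cells cultured with a source of NO. Contractile, matrix, cell cycle, ribosomal protein and interferon response genes were lower in the NO donor library, some of them by more than 10-fold. Cytokine and chemokine genes, NRF2 targets, p53 targets, metallothioneins and proteasome subunits were higher. The transcripts of USP9X and NOTCH1 lay close to the control level at the authors' scaling, and above it at total count scaling, by 0.74 and 0.42 log2 units. Among the 6972 genes at or above the median of mean expression, 780 were at least 1 log2 unit higher and 1117 at least 1 log2 unit lower. Of the genes that differed by at least 1 log2 unit, 41.1% were thus higher. This split depended on the scaling. With each library scaled to its total count, every log2 ratio was 0.60 larger. By the same cut, 2244 genes were then higher and 587 lower, so 79.3% of the genes past it were higher. In the authors' deposited table, 7123 of 13943 tested genes had an adjusted p below 0.05, 3442 of them higher and 3681 lower; that p rests on the columns and is no test of the treatment.

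**Figure D1:**
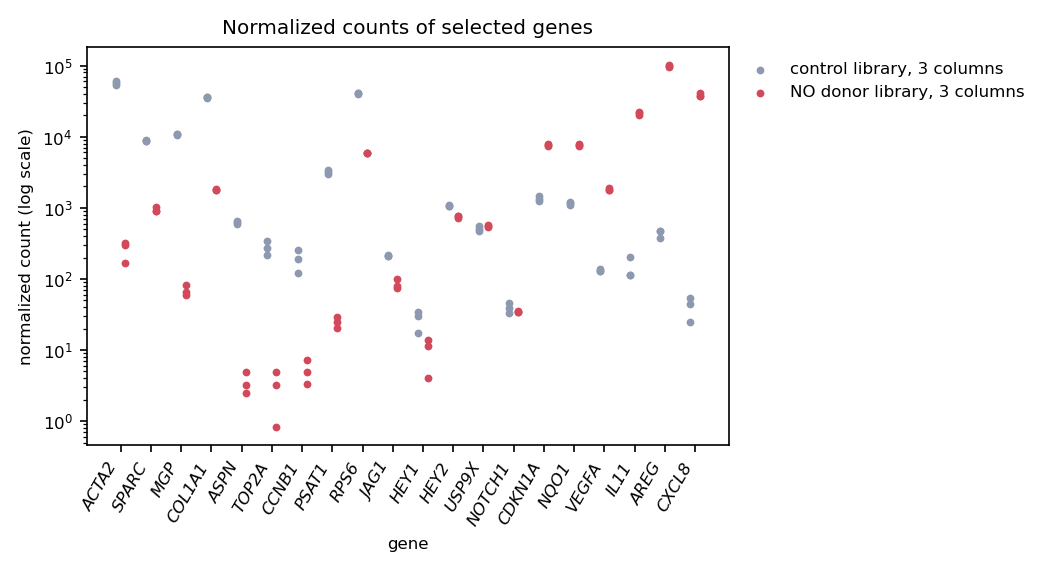
Normalized counts, on a log scale, of 20 genes in the control library (grey) and the NO donor library (red), with a point for each of the 3 columns of a library. ACTA2 lay between 53977 and 60430 in the control columns and between 169 and 325 in the NO donor columns, whereas CXCL8 lay between 24.8 and 53.8 and between 37173 and 40723.

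Contractile genes, which encode the actin, myosin and associated proteins of the myofibroblast state, were lower as a group. All 24 measured members were lower by at least 0.5 log2 units, with a median log2 ratio of −3.25. ACTA2, the smooth muscle actin used to mark activated valve interstitial cells, is annotated on chromosome 14 from 100868145 to 100886732 of Sscrofa11.1. It had a normalized count of 57046 (95% interval 56750 to 57343) in the control and 263 (247 to 280) in the NO donor library, 217-fold lower (203 to 231). MYH11, smooth muscle myosin heavy chain (chromosome 3, 7002667 to 7143093), was 216-fold lower (109 to 502), from 1172 counts to 8. ACTG2, enteric smooth muscle actin, had 1382 counts in the control and 2 in the NO donor library, a ratio of 1019.6 (282 to 8427). DES, the muscle intermediate filament desmin, had 650 counts in the control and 0 in the NO donor library. It was 319.7-fold lower at a floor of 3 counts per library, and at least 259-fold lower by the exact 95% interval. Its normalized counts in the control columns ran from 103 to 499. The contractile list took 2.92% of all counts in the control and 0.404% in the NO donor library.

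Extracellular matrix genes were lower in 29 of 37 measured members and higher in 1, with a median log2 ratio of −1.80. COL1A1, the alpha 1 chain of type I collagen (chromosome 12, 26379087 to 26397180), was 20.1-fold lower (19.6 to 20.6), at 35938 in the control and 1787 in the NO donor library. ASPN, a small proteoglycan that binds collagen, was 176-fold lower (103 to 332), EFEMP1, a fibulin, 68.3-fold (37.8 to 138), and ELN, elastin, 47.5-fold (28.5 to 85.6). CTHRC1, a secreted protein of matrix-producing fibroblasts, was 134-fold lower and LRRC17 247-fold lower. Of the 15 measured markers of valve interstitial cells, 9 were lower and 4 higher, with a median of −2.21. THY1 was 14.1-fold lower and S100A4 10.4-fold lower. This list also holds COL1A1 and MGP, which are given with other lists, so it is not separate from them. TGF-beta and BMP response genes were lower in 14 of 23 members and higher in 3, with a median of −1.14; under total count scaling 13 were lower and 9 higher, with a median of −0.54. Among them TGFB3, a TGF-beta ligand, had a log2 ratio of −4.17, while LTBP2 was 8.63-fold lower and CTGF 7.22-fold lower. WNT pathway genes were also lower in 14 of 23 and higher in 3, with a median of −1.14, or in 12 and 7 with −0.54 under total count scaling, including SFRP2 at 4.70-fold and DKK3 at 4.52-fold, both secreted WNT modulators. Matrix proteases and their inhibitors went both ways, 12 higher and 9 lower with a median of 0.38; under total count scaling 14 were higher and 5 lower, with a median of 0.98. ADAMTS5, an aggrecanase, was 24.1-fold higher (19.9 to 29.6) and CTSL, cathepsin L, 22.9-fold higher, whereas ADAMTS9 was 15.2-fold lower. MMP3, stromelysin 1, had 1006 counts in the NO donor library and 1 in the control, a ratio of 682 (122 to 26956).

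Cell cycle genes were lower in the NO donor library. Of 28 G2/M members 27 were lower by the 0.5 rule and none was higher, with a median log2 ratio of −4.55. CENPF, a kinetochore protein, was 101-fold lower (61.0 to 181), TOP2A, the topoisomerase of dividing cells, 93.5-fold (51.9 to 188), KIF23 62.9-fold and CCNB1, cyclin B1, 37.5-fold (23.8 to 62.9). Of 26 S phase members 22 were lower, with a median of −1.66; RRM2, a subunit of ribonucleotide reductase, was 15.5-fold lower (12.1 to 20.2). p53 target genes were higher in 15 of 22 members and lower in 3, with a median of 0.82. CDKN1A, the cyclin-dependent kinase inhibitor p21, was 5.69-fold higher (5.49 to 5.90), FAS, a death receptor, 4.20-fold, XPC, a DNA damage sensor, 3.71-fold, and MDM2, the ubiquitin ligase of p53, 3.29-fold.

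Ribosomal protein genes were lower in all 52 measured members by the 0.5 rule, and in 49 of them under total count scaling. Their median log2 ratio was −1.97, or −1.37 under total count scaling. RPS6 was 6.90-fold lower (6.80 to 7.01). The list took 21.6% of the control counts and 9.64% of the NO donor counts. RN5-8S, the gene of 5.8S ribosomal RNA, lies on a sequence not placed on a chromosome. It had 3378 counts in the control and 32 in the NO donor library, 156-fold lower (110.1 to 228). How far these counts follow the level of this RNA was not tested, so no change of ribosomal RNA is read from them. Interferon response genes were lower in 18 of 21 members and higher in none, with a median of −1.78, or in 12 and 2 under total count scaling, led by IFI6 at 20.8-fold (19.4 to 22.3) and ISG12(A) at 10.4-fold. Cholesterol synthesis genes were lower in 12 of 20 and higher in 3, with a median of −0.91, but under total count scaling 6 were lower and 6 higher, with a median of −0.31. Among them FDPS was 2.90-fold lower and SQLE 2.74-fold lower, whereas HSD17B7 was 9.50-fold higher.

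Among the named genes, the inflammatory genes CCL20 and CXCL8 held the largest ratios above the control. Of 26 measured members of the inflammatory list 17 were higher and 5 lower, with a median log2 ratio of 1.72. The list took 1.64% of counts in the NO donor library and 0.130% in the control. CXCL8, the neutrophil chemokine interleukin-8 (chromosome 8, 69932646 to 69935861), was 970.4-fold higher (797 to 1194), from 39.7 to 38547. IL11, a cytokine of the interleukin-6 family, was 152-fold higher (137 to 169.6) and IL1A, interleukin-1 alpha, 345-fold (135 to 1267). CCL20, a chemokine, had 3000 counts in the NO donor library and 1 in the control, a ratio of 2033 (365 to 80332). Outside the list, AREG, amphiregulin (chromosome 8, 70417935 to 70428106), was 228-fold higher (215 to 242) and took 1.71% of all NO donor counts against 0.00498% in the control. EREG, epiregulin, which lies beside it from 70351316 to 70372530, was 124-fold higher (85.3 to 189). Among the other genes with the largest ratios, IL1RL1, the interleukin-33 receptor, was 108-fold higher, CXCL14 89.6-fold and MUC12 59.5-fold. Immediate early genes were higher in 15 of 23 members and lower in 2, with a median of 1.12; IER3 was 12.3-fold higher, NR4A2 10.5-fold and ATF3 8.62-fold.

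Antioxidant and stress genes differed in part. NRF2 targets were higher in 14 of 26 members and lower in 4, with a median of 0.82. OSGIN1 was 16.6-fold higher (12.4 to 22.7), PRDX6, a peroxiredoxin, 7.02-fold, NQO1, a quinone reductase, 6.65-fold and SLC7A11, the cystine transporter, 6.36-fold. All 5 measured metallothionein and zinc genes were higher, with a median of 3.35; MT-2B, a metallothionein, was 57.5-fold higher (51.2 to 64.9). Proteasome subunits were higher in 18 of 32 members and lower in none, with a median of 0.56, or in 30 under total count scaling, and PSMD8 was 2.53-fold higher. Glycolysis and hypoxia genes were higher in 15 of 31 and lower in 1, with a median of 0.48, or in 24 and 1 under total count scaling; VEGFA, the vascular growth factor, was 13.8-fold higher (12.3 to 15.4) and SLC2A3, a glucose transporter, 12.4-fold. The other antioxidant enzymes had a median of −0.20, which became 0.40 under total count scaling, with SOD3 6.98-fold lower and GPX3 4.05-fold higher. The integrated stress and unfolded protein list had 7 of 25 members higher, 10 lower and a median of −0.17, which became 0.42 under total count scaling. In it ATF3, also an immediate early gene, was 8.62-fold higher, and the serine and asparagine synthesis genes PSAT1, PHGDH and ASNS were 129-fold, 14.7-fold and 9.15-fold lower. Heat shock genes had a median of 0.32, nuclear genes of oxidative phosphorylation 0.19 and iron handling genes −0.09; under total count scaling these became 0.92, 0.78 and 0.50. Of the oxidative phosphorylation genes 4 of 23 were higher and 3 lower, or 16 and 0 under total count scaling. FTL, ferritin light chain, was 1.89-fold higher and FTH1, ferritin heavy chain, 1.96-fold lower. Under total count scaling their log2 ratios were 1.51 and −0.38, so FTH1 no longer passed the 0.5 rule.

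Osteogenic genes showed no common direction, with 6 of 16 members higher, 7 lower, a median of 0.10 and a mean of −0.61; under total count scaling 9 were higher and 6 lower, with a median of 0.70. SPP1, osteopontin, was 32.4-fold higher (25.6 to 41.7), SLC20A2, a phosphate transporter, 3.09-fold higher and SPARC, osteonectin, 9.20-fold lower. RUNX2, the osteoblast transcription factor, chosen after its values were seen, had a log2 ratio of 0.03 (−0.16 to 0.21) at the authors' scaling. Total count scaling adds 0.60 to every log2 ratio, which puts RUNX2 past the size rule for higher. The reading of RUNX2 therefore depended on the scaling. Calcification inhibitors were lower in 7 of 12 members and higher in 3, with a median of −1.35. MGP, matrix Gla protein (chromosome 5, 57665272 to 57669360), was 157-fold lower (139 to 178), at 10851 in the control and 69.1 in the NO donor library. ANKH, a pyrophosphate transporter, was 6.03-fold lower, whereas SPP1, which this list also holds, was higher. Chondrogenic genes were lower in 7 of 11 and higher in 3, with a median of −0.75; under total count scaling 4 were lower and 3 higher, with a median of −0.16. SOX9 was 2.53-fold lower.

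On the NOTCH axis, USP9X (chromosome X, 36736049 to 36888702) had a normalized count of 504 in the control and 555 in the NO donor library, a log2 ratio of 0.14 (0.04 to 0.24), in the same direction in 8 of the 9 pairings of columns; total count scaling gave 0.74. NOTCH1, which lies on a sequence not placed on a chromosome, had 98 counts in the control and 128 in the NO donor library. Its log2 ratio was −0.18 (−0.57 to 0.22), an interval that held 0 at the authors' scaling. Total count scaling gave 0.42, so the reading of NOTCH1 depended on the scaling. Of 10 measured NOTCH target genes 7 were lower and 2 higher, with a median of −0.63. The lower ones include HES1, whose counts were too low to compare. Under total count scaling 4 were lower and 3 higher, with a median of −0.03. HEY1 had 36 counts in the NO donor library and 70 in the control, a log2 ratio of −1.52 (−2.14 to −0.92). HEY2 had a log2 ratio of −0.52 (−0.60 to −0.44) and MYC −0.54, but both turned positive under total count scaling, at 0.0778 and 0.0553. JAG1, a NOTCH ligand, had a log2 ratio of −1.31 (−1.51 to −1.10), NOTCH3 −1.29 and LFNG −0.71, whereas GATA2 had 1.16 and HES4 0.92 (0.00 to 1.91). LFNG moved to −0.12 under total count scaling. CCND1 had −0.06, which became 0.53 under total count scaling. HES1, with 3 and 8 counts in the NO donor and control libraries, and NRARP, with 6 and 2, were too low to compare. The components of the pathway had 10 of 30 members higher and 7 lower, with a median of −0.02 and a mean of 0.0446; the median became 0.58 under total count scaling. MAML2, a coactivator, was 3.39-fold lower. NO and cGMP pathway genes were lower in 8 of 13 and higher in 2, with a median of −0.78; under total count scaling 4 were lower and 3 higher, with a median of −0.19. PDE1A, a phosphodiesterase, was 4.91-fold lower and DDAH1, which degrades an inhibitor of NO synthases, 2.68-fold lower.

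Markers of other cell types that a valve culture could hold were set beside CXCL8, at 38547 in the NO donor library and 39.7 in the control, and beside the contractile list, which summed to 23379 and 255727. The 8 leukocyte markers with a value summed to a normalized count of 203 in the NO donor library and 185 in the control, most of it CD14 at 151 and 160.1. Their median log2 ratio over 7 measured genes was 1.16, with 5 higher and 1 lower; CD14 had −0.08, which became 0.51 under total count scaling. The 9 endothelial markers with a value summed to 455 and 825, most of it PECAM1, at 209.7 and 326, EGFL7, at 153 and 89.9, and ERG, at 72.3 and 375. Over 7 measured genes the median was −0.64, and without the member of largest ratio it was 0.0662. The 5 cardiomyocyte markers with a value summed to 503 and 90.7, with NPPB, B-type natriuretic peptide, at 404 and 9.63. The only epithelial marker with a value, CLDN7, stood at 15.8 and 6.02 and was chosen after its values were seen. None of the 26 mitochondrially encoded genes had a value, so this sign of RNA quality could not be read.

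Against 10000 random lists of the same size matched on mean expression, 20 of 31 lists lay outside the central 95%, 12 below and 8 above. Some lists share members, such as COL1A1 in the matrix and valve interstitial lists and MGP in the calcification inhibitor and valve interstitial lists. The 20 are therefore not separate results. The contractile, matrix, valve interstitial, G2/M, S phase, ribosomal, interferon and TGF-beta lists lay at percentile 0. Other low lists were the cholesterol list at 0.02, WNT at 0.03, calcification inhibitors at 0.23 and the NO and cGMP list at 1.23. The inflammatory, immediate early, NRF2 and proteasome lists lay at percentile 100, the p53 and metallothionein lists at 99.99, glycolysis and hypoxia at 99.93 and matrix proteases at 98.69. Inside the central range were leukocyte markers at 96.96, heat shock at 94.28, oxidative phosphorylation at 93.22, osteogenic genes at 68.65, iron handling at 48.19, NOTCH components at 42.16, antioxidant enzymes at 38.84, the stress response list at 28.68, endothelial markers at 12.31, NOTCH targets at 8.59 and chondrogenic genes at 5.79. These percentiles describe the genes of these libraries and are no test of the treatment.

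**Figure D2:**
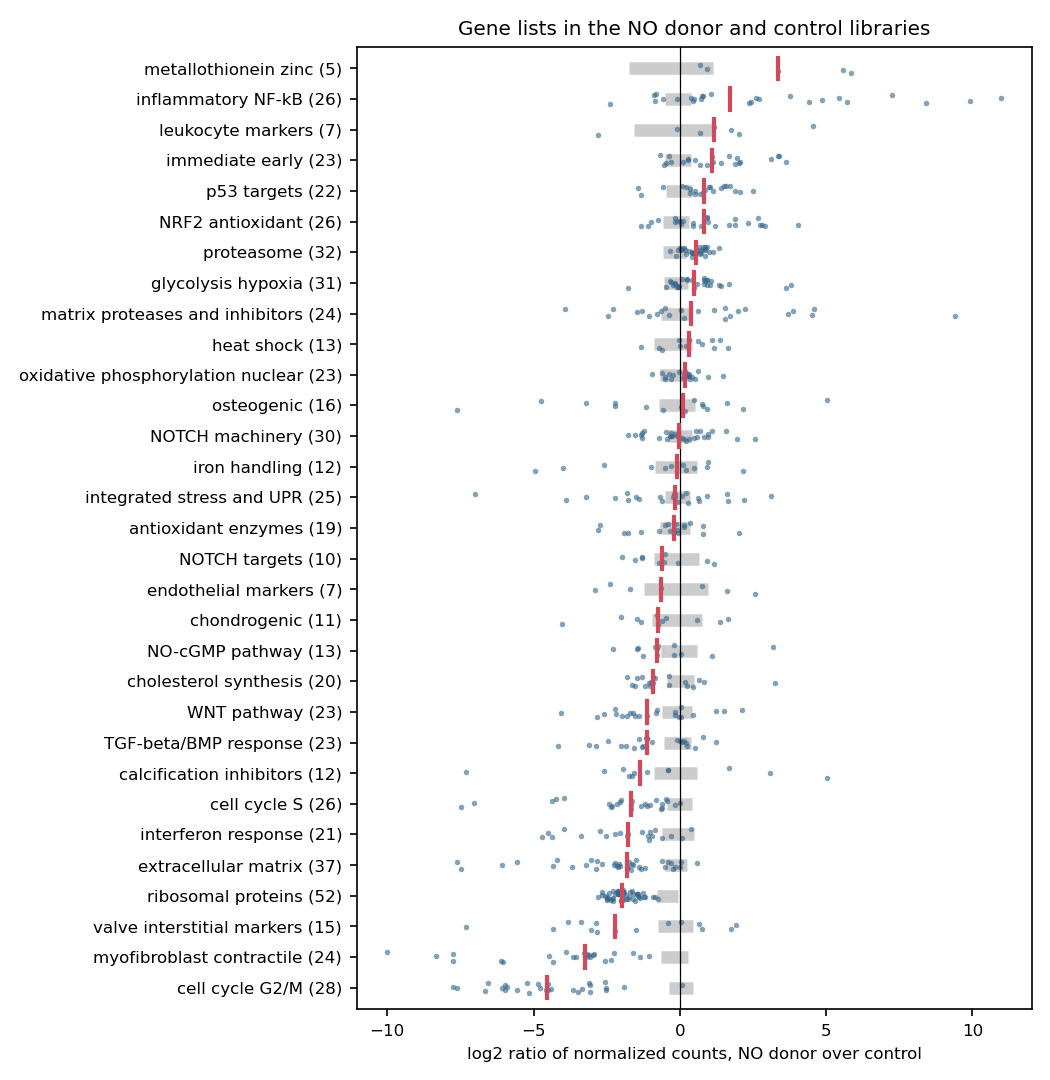
Log2 ratio of normalized counts, NO donor over control, for the measured genes of 31 lists (points, number of genes in brackets), with each list's median (red line) and the central 95% of medians of matched random lists (grey bar). The medians run from −4.55 for the G2/M list to 3.35 for the metallothionein and zinc list, at the authors' scaling; total count scaling moves every point by 0.60 to the right.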

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

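The scaling by TMM and by total counts, the ratio against the authors' fold change, the size counts with no minimum mean and the edgeR test were chosen after seeing the data; the other alternatives were planned. Of 243 list alternatives other than scaling, 221 kept the direction and the side of the central 95%, and 19 of 31 lists did so in each of theirs. The 62 scaling alternatives move every gene with counts in both libraries alike, so percentiles were nearly fixed by construction and say nothing of stability, but 4 medians turned positive under total count scaling: NOTCH components (0.58), antioxidant enzymes (0.40), the stress response list (0.42) and iron handling (0.50). Among lists inside the central range, the sign also changed for NOTCH components by the mean (0.0446), with every gene (0.0237) and by the Wald score (0.0661), and iron handling at or above the median mean (0.225) and without its largest member (0.113). Osteogenic genes did so by the mean (−0.61) and endothelial markers without their largest member (0.0662). In the authors' deposited table, requiring a log2 fold change of at least 1 left 1474 genes higher and 2196 lower, and genes at or above the median mean left 2514 higher and 2431 lower, fewer by construction. By size, 2244 genes were higher and 587 lower under total count scaling, and 2018 and 2821 with no minimum mean. HEY2 and MYC reversed under total count scaling, to 0.0778 and 0.0553, because that scaling adds 0.60 to every log2 ratio. Lists that left the outer range were calcification inhibitors by the mean (−0.74), matrix proteases against unmatched lists (0.38) and without their largest member (0.13), and S phase genes at or above the median mean (−0.66). The NO and cGMP list did so by the mean (−0.44), with every gene (−0.21) and by the Wald score (−2.15), and cholesterol genes by the mean (−0.49) and at or above the median mean (−0.38). Lists that entered the outer range were osteogenic genes at or above the median mean (0.77), leukocyte markers with every gene (1.20) and against unmatched lists (1.16), and by the Wald score chondrogenic genes (−2.12), endothelial markers (−2.47) and heat shock genes (5.54). The cause was not tested for these lists. The edgeR quasi-likelihood test on the recovered counts, which compares those libraries, not the conditions, called 9049 of 11665 genes with its low-count filter (4617 higher, 4432 lower) and 9881 of 13943 without it (5091 and 4790). The planned edgeR, DESeq2 and pseudocount fits across libraries, with replicates left out or as a block, were not run: they need at least 2 libraries per group. No paired analysis was possible because each group had 1 library. Depth limits genes with a few counts, such as HES1, NRARP, CCL20 and MMP3, whose ratios have wide intervals.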

Other observations

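The lists in this and the next paragraph were made after the libraries had been compared. Those of epidermal growth factor receptor ligands and of the vacuolar ATPase were made after their values had been seen, the others before. In the list of receptor ligands, 4 of 5 measured genes were higher and 1 lower, with a median log2 ratio of 2.54. HBEGF, which encodes such a ligand, had 2.54, equal to this median, and adds no separate support. Vacuolar ATPase subunits, which acidify endosomes and lysosomes, were higher in 11 of 17 and lower in 4, with a median of 0.57. Other lysosomal genes had 4 of 20 higher and 3 lower, a median of −0.08, which became 0.52 under total count scaling, and percentile 40.41 among matched random lists. Integrins were lower in 10 of 18 and higher in 5, with a median of −0.94 at percentile 0.27; under total count scaling 8 were lower and 6 higher, with a median of −0.34. ITGA8, the integrin alpha 8 chain, had a log2 ratio of −4.10, whereas ITGB5 had 2.01 and ITGA3 1.86; these and NOP56 were picked after their values were seen.

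Nucleolar and RNA polymerase I genes were higher in 8 of 16, lower in 1 and within 0.5 in 7, with a median of 0.54 at percentile 98.67, with 12 higher and none lower under total count scaling, among them NOP56 at 1.61. Mitochondrial ribosomal proteins were higher in 29 of 77 and lower in 6, with a median of 0.33 at percentile 99.86; under total count scaling 62 were higher and 2 lower, with a median of 0.92. Initiation factors outside the 5′ terminal oligopyrimidine class were higher in 7 of 13, lower in none and within 0.5 in 6. Their median was 0.55 at percentile 99.42, and all 13 were higher under total count scaling. The shift of 0.60 by that scaling alone passes the 0.5 rule, so the counts under it in this paragraph add no support. Aminoacyl-tRNA synthetases had a median of −0.39 at percentile 7.62 and amino acid carriers −0.16 at 20.95; under total count scaling these became 0.21 and 0.43. By share of counts, TMSB4X, thymosin beta 4, took 1.97% of the control and 0.265% of the NO donor library, and TIMP1, an inhibitor of matrix proteases, 0.217% and 1.29%; both were chosen after their values were seen.

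Of the tests that follow, those on transcript length, on abundance and on terminal oligopyrimidine transcripts were set before their result was seen, and those on scaling, other cell types, dissociation and cell numbers after it. The count of short abundant genes was also made after it.

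Ribosomal protein genes were lower in the NO donor library, with a median log2 ratio of −1.97. Under total count scaling, which adds 0.60 to every log2 ratio, the median was −1.37, so the list was lower under either scaling. Total counts include the abundant genes, so this value cannot decide whether a few of them distorted the scaling. The 157 other genes in the same range of means had a median of −0.61. That value argued against a lower level of abundant transcripts in general as the whole cause. Of these genes 85 were lower and 35 higher by the 0.5 rule, so abundance may carry part of the difference. A loss of short transcripts as the whole cause was argued against by a median of −0.22 over 513 genes matched on length and mean, although these were longer, with a median transcript of 1330 bases against 746.5; the 24 other abundant genes up to that length had −0.97, so length may carry part of the difference. A shared change of transcripts with a 5′ terminal oligopyrimidine tract, which many translation genes carry, had the values it needs: 18 other such transcripts, fixed as a list, had a median of −1.47 at percentile 0.04, with 17 lower and none higher. EEF1A1, left out of that list because its value of −4.12 had been seen, is of this class; as a hypothesis, this class may have differed as a group, while reads shared with processed copies of these genes were not tested.

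Inflammatory genes were higher in the NO donor library, with a median log2 ratio of 1.72. The CXCL8 level that leukocytes would bring was not measured, so a comparison with it cannot decide whether leukocytes were the source. Their 8 markers with a value, of 20 listed, together reached 0.527% of the normalized count of CXCL8. CD14, the most abundant of them, was at 151 in the NO donor library and 160.1 in the control. TYROBP, abundant in myeloid cells and picked outside the rule for named genes, was at 1.09 and 7.62. Of the 7 measured markers 5 were higher and 1 lower. Their median log2 ratio was 1.16, so a small share of leukocytes was not excluded. Stress during cell dissociation could raise such genes too, and the immediate early list, which it would also raise, lay at percentile 100. With 1 library per group, handling and the NO donor cannot be told apart for these genes, and the effect of the donor itself stays open, as untested.

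Contractile and matrix genes were lower in the NO donor library. The contractile list stayed lower under total count scaling, with a median of −2.65. That scaling is a fixed shift of 0.60, so it shows only that the choice between these scalings did not set the direction. The 17 of 38 endothelial and leukocyte markers with a value summed to 0.651 times the control at the authors' scaling. Total count scaling moves that ratio up by 0.60 log2 units. These values argue against such cells taking the place of most interstitial cells, only as far as those markers reach. The leukocyte markers alone summed to 203 against 185, so for a smaller share of leukocytes this stays open. PECAM1 was at 209.7 and 326, EGFL7 at 153 and 89.9, CD14 at 151 and 160.1 and ERG at 72.3 and 375 in the NO donor and control libraries. For epithelial cells or cardiomyocytes this stayed open, with 6 of 28 markers having a value and a sum 5.37 times the control, in which NPPB was at 404 and 9.63. Fewer contractile cells, each unchanged, and a lower level in every cell cannot be told apart without values per cell: log2 ratios over the contractile list spanned 8.94 units, which either could give, and the effect of the donor stays open, as untested.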
